A study of Homo sapiens with 12 samples.

How the data were processed

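Polyadenylated RNA of NOMO-1 cells was sequenced as input and m6A IP libraries for 3 guides with 2 libraries of each kind, 12 in all. Reads were aligned with STAR to GRCh38, per the submitters' processing notes, which give no STAR version. The peak caller, its version, the gene annotation and the choice of sgNS libraries are not given in the sources used here. The authors deposited 4 tables, and per the file headers each row is a window of a transcript with its blocks. The columns used were the log2 fold change of the difference, the log10 of its FDR, the log10 of its p-value, the log10 of the p-value and FDR of IP over input, and the fold enrichment of IP over input, all as deposited by the authors. No value per library was used here, so depth per library is unknown and limits the precision of each fold change in a way the tables do not show. In windows with the strongest enrichment the deposited p-values of the difference reached no further than 0.504 to 0.514, as a one-sided test gives. The tables give no spread between replicates. The table number was read as the replicate number.

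A window was called when the deposited FDR was under 0.05, lower or higher by the sign of its log2 fold change. Windows of 2 tables were the same when they lay on the same strand, carried the same gene name and shared at least 0.5 of the bases of each, counted over blocks and matched 1 to 1. A window called in the same direction in both tables of a guide, or in all 4 tables, was counted as shared. Agreement was Spearman's rho and the covariance of log2 fold changes across matched windows. The value expected of unchanged knockouts that share a control was simulated with equal noise in every library. For position, windows were classed by their distance to the ends of their gene in the RefSeq table for GRCh38, within 1000 bases or not. At least 98.2% of the windows in each table had a gene with ends. The design planned transcript regions and sequence motifs, which need exons and a genome that were not used here.

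The 16 gene lists were fixed before the data were examined: S-adenosylmethionine and methionine metabolism, m6A writers, erasers and readers, branched-chain amino acid metabolism, AML and leukaemia stem cells, myeloid differentiation, translation initiation factors, cytoplasmic ribosomal proteins, p53 and apoptosis, cell cycle, DNA damage repair, spliceosome, interferon and innate immunity, integrated stress response, lymphoid and erythroid markers, mitochondrially encoded genes, and abundant nuclear and long non-coding RNAs. List genes were tested among genes with a call by Fisher's exact test, two-sided, per table and direction, with Benjamini-Hochberg adjustment over 128 tests. The background was every gene with a window in that table. Counts adjusted over the list alone used the deposited p-values of the list's windows. Each list's median of gene mean log2 fold changes was also placed among 10000 random lists matched on the number of windows per gene, for lists of at least 5 genes.

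METTL16 and MAT2A were named first. For each guide, the 10 lower and 10 higher windows with the largest mean log2 fold change among windows called in 1 direction in both tables were named, with 1 window per gene. The same was done over all 4 tables, and all were named where fewer than 10 passed. Up to 4 members of each list called in 1 direction in both tables of a guide could be named. The deposited coordinates start from 0 and are given here from 1. Between 215 and 282 rows per table shared their exact start and blocks with another row, first listings included, and all were kept. Near copies, such as those of EIF4A1 and SENP3-EIF4A1, are not in that count.

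The alternatives set beforehand were an FDR of 0.01, an absolute log2 fold change of at least 1, a fold enrichment of at least 2, other overlaps, 1 row per gene, centring, leaving out either replicate, and random lists without matching. Those added after seeing the data were enriched windows alone, windows of overlapping genes counted once, a two-sided p-value, and a shift of each table by the median of its enriched windows. After that shift, two-sided p-values were recomputed from a normal approximation whose standard error came from the deposited p-value. Calls lost after it can therefore come from the two-sided test as well as from the shift, and counts with a two-sided p alone are given beside it. The steps were checked on simulated data. Matching recovered 100% of windows moved by 0.1 of their length and 0% of those moved by 0.75. The list test and the percentile were checked in the 15110 genes of the replicate 1 table of sgMETTL16-2. By its unadjusted p, the list test called 74% of 40-gene lists with 4 seeded members and 100% of those with 8. The lists in the Results were judged by the adjusted p, which is stricter, and recovery at that threshold was not checked. The percentile placed 88% of lists shifted by 0.25 in log2 beyond the central range. Random lists fell beyond it in 6%, 12% and 2% of runs with shifts of 0.25, 0.5 and 1.0. Fold changes were shuffled over windows in this check, so windows of 1 gene were independent there. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.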

Results

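N6-methyladenosine (m6A) on polyadenylated RNA was mapped in NOMO-1 cells, a human acute myeloid leukaemia (AML) line, after knockout of the RNA methyltransferase METTL16. The cells carried guide sgMETTL16-1, guide sgMETTL16-2 or the control guide sgNS. RNA was sequenced before (input) and after immunoprecipitation (IP) with an m6A antibody, which makes 12 libraries: 2 input and 2 IP libraries for each of the 3 guides. The question set by the series is which m6A sites depend on METTL16. The results come from the authors' deposited tables of their own comparisons, 4 in all, 1 for each knockout guide and replicate number. Each table lists windows of transcripts, with a fold enrichment of IP over input and a log2 fold change between knockout and sgNS. The tables held between 70002 and 79372 windows on between 14872 and 15212 genes. The median window was 121 bases long in each table. The number of reads per library is unknown, and no value below has a replicate error of its own, because each table stands for 1 guide and 1 replicate number. Nothing in the labels says that replicate numbers stand for separate cultures. A negative log2 fold change is read as less m6A in the knockout, the usual convention of the software whose column names the tables carry. The tables do not state it, and with the opposite convention every direction below would turn. A window is called when the authors' FDR of the difference is under 0.05, and enriched when their FDR of IP over input is under 0.05.

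METTL16 itself had no called window in any of the authors' deposited tables, which list 5 to 7 windows on it. Its most enriched window in the sgMETTL16-2 replicate 1 table (chromosome 17, 2419949 to 2420578) had a log2 fold change of -0.18 and an FDR of 0.659 in the authors' deposited table. These windows compare methylation relative to input and not the amount of METTL16 RNA, so they do not check the knockout.

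MAT2A, the enzyme that makes S-adenosylmethionine and the best known messenger RNA target of METTL16, was lower at its 3′ end in all 4 of the authors' deposited tables. In the authors' deposited tables of sgMETTL16-1, the window from 85544625 to 85545161 on chromosome 2 was at -0.71 (FDR = 5.37e-05) in replicate 1. The authors' deposited table of replicate 2 of that guide gave -0.81 (FDR = 0.0151) for 85544923 to 85545161. For sgMETTL16-2, the authors' deposited tables gave -0.73 (FDR = 7.76e-05) in replicate 1 and -0.61 (FDR = 0.123, not called) in replicate 2. In GRCh38 the gene runs from 85539168 to 85545281 on the plus strand, so these windows end 90 to 150 bases before its 3′ end. A second MAT2A window further upstream, which starts at 85543703 in the replicate 1 table of sgMETTL16-1, was not called. Its log2 fold changes in the authors' deposited tables were 0.11 and -0.69 for sgMETTL16-1 and -0.32 and -0.94 for sgMETTL16-2. GGCX, a vitamin K-dependent carboxylase gene on the opposite strand, overlaps the MAT2A 3′ end and was listed in the authors' deposited tables with nearly the same windows and values, -0.70 for sgMETTL16-1 in replicate 1 and -0.64 and -0.68 for sgMETTL16-2. In replicate 2 the calls of the 2 genes differed: MAT2A but not GGCX was called lower with sgMETTL16-1, and GGCX but not MAT2A with sgMETTL16-2. The reads of the 2 genes could not be told apart here. Of the 3′ windows 1 was enriched, with an FDR of IP over input in the authors' deposited tables of 0.215, 0.265, 0.00708 and 0.0759 in the same order.

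**Figure D1:**
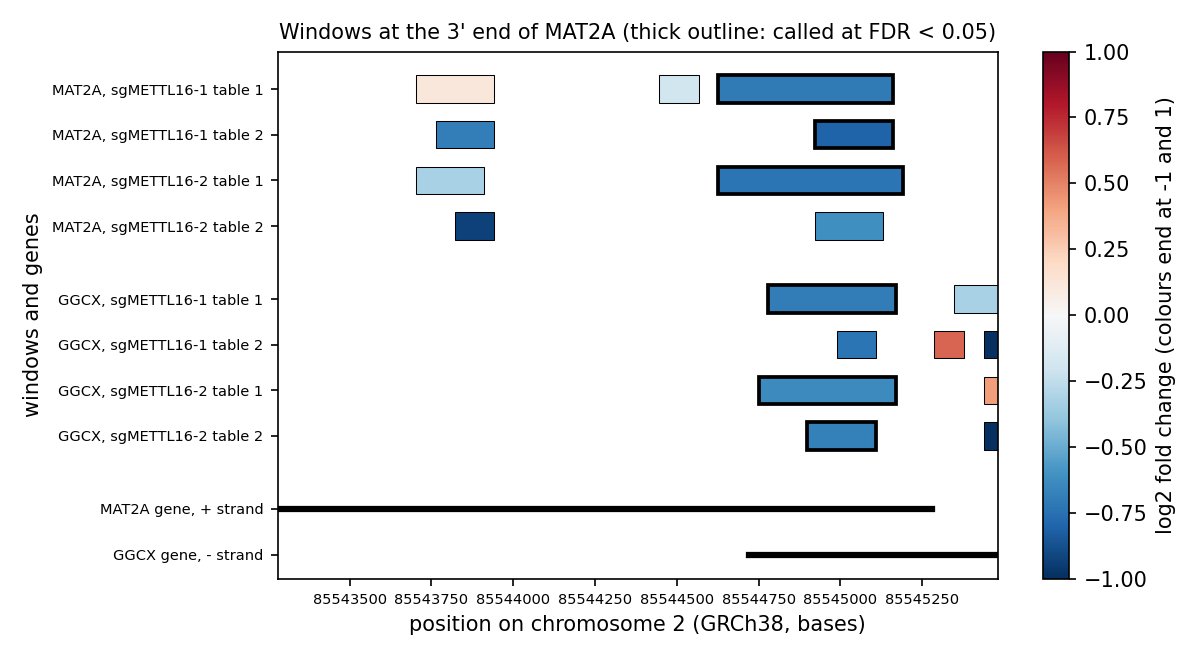
Windows listed for MAT2A and GGCX over the last 2 kb of MAT2A, by position on chromosome 2 (GRCh38, bases) and table, coloured by the log2 fold change in the authors' deposited tables; a thick outline marks an FDR under 0.05. The 3′ windows of MAT2A lie between -0.61 and -0.81 in the 4 tables, and the GGCX windows on the other strand overlap them.

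With guide sgMETTL16-1, 9 windows were called lower and 4 higher in both replicate tables, and 20 were called in opposite directions. After each table was shifted by the median of its enriched windows, an alternative chosen after seeing the data, 6 of the 9 and 1 of the 4 were still called in both. The p after the shift is two-sided, and a two-sided p alone left 8 lower and 2 higher. With an overlap of 0.8 the counts were 4 lower and 2 higher, and with a fold enrichment of at least 2 they were 0 and 2. The lower ones included EIF4A1, an RNA helicase of translation initiation, at chromosome 17 (7577646 to 7577885), with -0.59 and -0.74 in the authors' deposited tables. The nonsense-mediated decay factor UPF3B was at -0.66 in each of the authors' deposited tables. The growth-related protein gene TPT1 was at -0.28 and -0.44, the ribosomal protein gene RPL32 at -0.32 and -0.31, and RPL37A at -0.14 and -0.21 in the authors' deposited tables. The splicing factor gene SRSF11 was at -0.27 and -0.33, and the cancer-testis genes XAGE1B and XAGE1E, which share 1 window, at -0.34 and -0.61 in the authors' deposited tables. SENP3-EIF4A1, a readthrough gene, has the EIF4A1 window listed a second time, at -0.56 and -0.78 in the authors' deposited tables. The 4 higher windows were those of TMEM259 (0.58 and 0.67), the interleukin 4 receptor gene IL4R (0.52 and 0.70), the myeloid transcription factor gene CEBPA (0.24 and 0.35) and the phosphatase gene PTPN7 (0.32 and 0.21) in the authors' deposited tables. After the shift CEBPA kept both calls, and TMEM259, IL4R and PTPN7 each lost that of replicate 2, where their shifted values were 0.53, 0.57 and 0.08. IL4R and PTPN7 lost 1 call with the two-sided p alone. Of the lower windows, those of XAGE1B, XAGE1E and RPL37A lost the call of replicate 1 after the shift. Among the 20 windows called in opposite directions, picked for mention after their values were seen, were those of the m6A writer subunit ZC3H13 (-0.41 and 0.52), the chaperone CALR (-0.17 and 0.37) and PTMA (-0.23 and 0.47) in the authors' deposited tables. Single tables called many more: 223 lower and 59 higher windows in the authors' deposited table of replicate 1, against 119 lower and 416 higher in that of replicate 2. Of 20031 windows matched between the 2 tables, independent calls would share 0.167 lower and 0.368 higher windows, and would oppose each other in 1.25. This expectation takes every window as equally likely to be called. The 20 opposite calls lay above it too, so shared calls above it do not by themselves show agreement.

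With guide sgMETTL16-2, 13 windows were called lower, 112 higher and 3 in opposite directions in the 2 replicate tables. After the shift, which moves every window of this guide down and so favours lower calls, 12 of the 112 higher windows were still called in both, and a two-sided p alone left 10 lower and 77 higher. With an overlap of 0.8 the counts were 2 lower and 67 higher, and with a fold enrichment of at least 2 they were 1 and 48. The largest decreases were in the zinc finger gene ZNF121 (chromosome 19, 9566057 to 9568120), at -0.79 and -1.38, and in WHSC1L1, a histone methyltransferase gene, at -0.85 and -1.17 in the authors' deposited tables. UPF3B (-0.86 and -0.66), CEBPZ (-0.69 and -0.82), the ubiquitin ligase gene PJA2 (-0.80 and -0.69) and SETDB2 (-0.71 and -0.72) followed in the authors' deposited tables. THOC2, of the messenger RNA export complex, was at -0.64 and -0.75, GGCX at -0.64 and -0.68, EIF4A1 at -0.53 and -0.61, and SENP3-EIF4A1 at -0.52 and -0.65 in the authors' deposited tables. The largest increases were in the Polycomb gene CBX8 (chromosome 17, 79794971 to 79797116), at 0.82 and 0.89, and in STK40, at 0.77 and 0.89 in the authors' deposited tables. ZBTB4 (0.75 and 0.59), the transcription factor gene JUN (0.58 and 0.73), the kinase gene DAPK3 (0.60 and 0.65) and ZBTB7B (0.74 and 0.49) were also higher in the authors' deposited tables. SLC7A1, a cationic amino acid transporter gene, was at 0.57 and 0.65, TNRC18 at 0.45 and 0.72, GATAD2A at 0.70 and 0.48 and RPRD2 at 0.60 and 0.56 in the authors' deposited tables. None of these 10 increases was still called in both tables after the shift, and ZBTB7B and GATAD2A were called in replicate 1 alone. Their fold changes moved less than their calls, with CBX8 at 0.69 and 0.75 and STK40 at 0.64 and 0.75 after the shift. With a two-sided p alone GATAD2A, JUN, RPRD2 and SLC7A1 kept both calls. The 3 windows called in opposite directions were of the ribosomal protein genes RPL27, RPL38 and RPS16, named after their values were seen, and each was lower in replicate 1 and higher in replicate 2 in the authors' deposited tables. The authors' deposited table of replicate 1 called 731 lower and 663 higher windows, and that of replicate 2 called 104 lower and 410 higher. Of 21192 matched windows, independent calls would share 0.208 lower and 7.83 higher windows, if every window were equally likely to be called. No shared call of either guide reached an absolute log2 fold change of 1 in both of its tables.

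**Figure D2:**
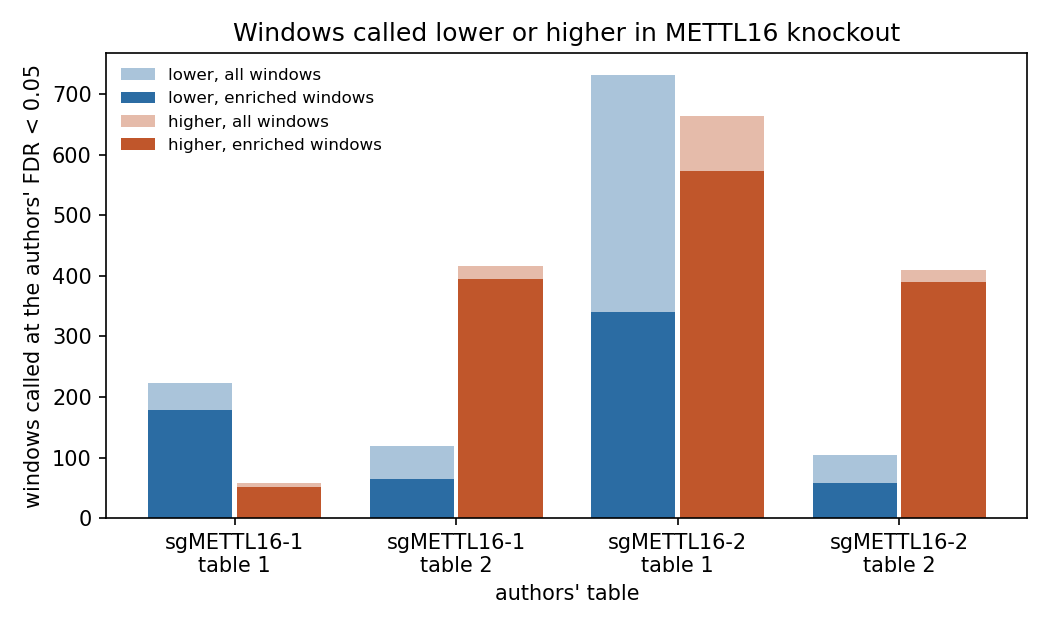
Number of windows called lower (blue) or higher (orange) at an FDR under 0.05 in each of the authors' deposited tables, with the enriched windows in full colour in front of all windows in light colour. The replicate 1 table of sgMETTL16-1 has more lower than higher calls, 223 against 59, and both replicate 2 tables have more higher calls, 416 against 119 and 410 against 104.

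Across both guides and both replicates, 6 windows were called in 1 direction in all 4 of the authors' deposited tables, 3 lower and 3 higher, of 6879 windows matched in all 4. The lower ones were EIF4A1 and its second listing SENP3-EIF4A1, between -0.52 and -0.78, and SRSF11 (chromosome 1, 70244751 to 70251000), between -0.24 and -0.33 in the authors' deposited tables. The higher ones were IL4R (chromosome 16, 27363189 to 27364508), between 0.52 and 0.70, CEBPA (chromosome 19, 33301040 to 33302564), between 0.24 and 0.49, and PTPN7 (chromosome 1, 202147013 to 202148117), between 0.21 and 0.32 in the authors' deposited tables. Counted by gene, whichever window carried the call, 8 genes were lower and 6 higher in all 4 tables with no call the other way. Without that condition 8 were lower and 8 higher. EEF2 and MYH9 were then added, and both also had lower windows in replicate 2 of sgMETTL16-1. Beyond the genes of the 6 windows, those called in 1 direction alone were B2M, MALAT1, NEAT1, TPT1 and UPF3B, lower, and IRF2BP2, P4HB and TMEM259, higher. All these genes were named after their values were seen. MALAT1 was called at -0.62 and -0.66 in replicate 1 of sgMETTL16-1 and at -0.51 in replicate 2 in the authors' deposited tables. B2M, of class I antigen presentation, was called at -0.23 and -0.36 with sgMETTL16-1 and at -0.53 and -0.26 with sgMETTL16-2 in the authors' deposited tables. By gene, 9 were lower after the shift, among them RPL32 and THOC2 but not NEAT1, and 1, CEBPA, was higher. A two-sided p alone left 6 lower and 4 higher genes. By window, after the shift 1 of the 3 higher windows, that of CEBPA, was called in all 4 tables, and 1 of the 3 was left with an FDR of 0.01 or a two-sided p. Of the 3 lower windows 1 was left with an overlap of 0.8 and 0 with a fold enrichment of at least 2.

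**Figure D3:**
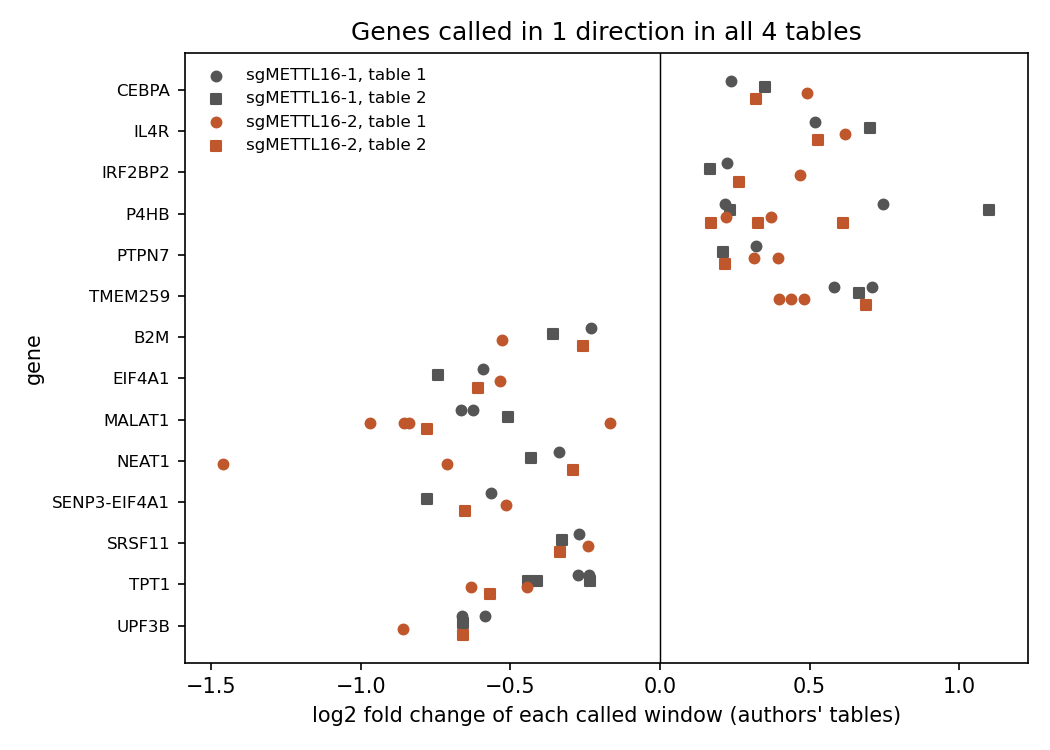
Log2 fold changes of each called window (horizontal axis) in the 14 genes called in 1 direction in all 4 of the authors' deposited tables, with grey points for sgMETTL16-1, orange for sgMETTL16-2, circles for replicate 1 and squares for replicate 2. CEBPA lies between 0.24 and 0.49 and EIF4A1 between -0.53 and -0.74.

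The fold changes agreed between guides within a replicate number and hardly between replicates of 1 guide. Across 39011 matched windows, Spearman's rho between the 2 guides was 0.563 in replicate 1, and across 37613 windows it was 0.604 in replicate 2. Between the 2 replicates rho was 0.0698 for sgMETTL16-1 and 0.146 for sgMETTL16-2. Pairs that share neither guide nor number gave 0.0775 and 0.139. These 6 correlations run across windows, which are not independent replicates, so no p is given. Which sgNS libraries entered a table is not stated. If the tables of 1 number shared them, 2 unchanged knockouts would give a rho of 0.483 in simulation. The covariance was 0.419 in replicate 1 and 0.450 in replicate 2, against a simulated 0.371 and 0.376 with no effect, and 0.0412 to 0.0843 between different numbers. In windows enriched in both tables the covariance was 0.0844 and 0.0818, against a simulated 0.0616 and 0.0565. The simulation gives every library equal noise, and a noisier control library would raise its values. Windows without enrichment also lay above it, with a rho of 0.594 in replicate 1 and 0.625 in replicate 2. A value above the simulated one therefore does not show an effect of METTL16 loss. The 2 guides shared 107 lower and 10 higher calls in replicate 1, where independent lists would share 2.48 and 0.264, and 40 lower and 181 higher calls in replicate 2, where they would share 0.224 and 3.14. The controls could not be split here, and the excess of shared calls may come in part or in full from shared controls. The expected counts also take every window as equally likely to be called.

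**Figure D4:**
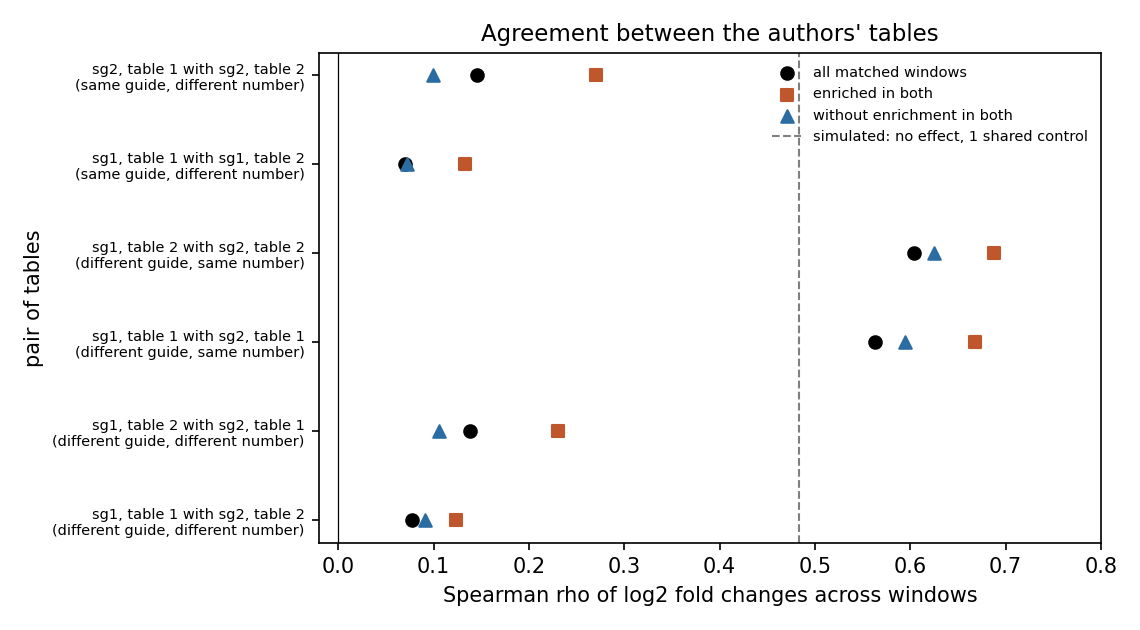
Spearman's rho of log2 fold changes across matched windows (horizontal axis) for the 6 pairs of the authors' deposited tables, where sg1 and sg2 stand for sgMETTL16-1 and sgMETTL16-2, with circles for all windows, squares for windows enriched in both tables and triangles for windows without enrichment in both. The 2 pairs of 1 number lie at 0.563 and 0.604 and the other 4 between 0.0698 and 0.146. The dashed line at 0.483 is the simulated value for unchanged knockouts that share a control, with equal noise in every library.

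Over all windows the median log2 fold change was 0 in each of the authors' deposited tables. Among enriched windows, 6426 and 8489 for sgMETTL16-1 and 7762 and 8586 for sgMETTL16-2, the median was -0.04 and 0.13, and 0.13 and 0.14, in the authors' deposited tables. Lower windows made up 79.1% of the calls in the replicate 1 table of sgMETTL16-1 (95% exact interval 73.9% to 83.7%) and 22.2% in replicate 2 (18.8% to 26.0%). For sgMETTL16-2 the shares were 52.4% (49.8% to 55.1%) and 20.2% (16.8% to 24.0%), and these intervals cover counting error only. With a two-sided p alone, calls were 174 lower and 43 higher, then 77 and 300, with sgMETTL16-1, and 505 and 433, then 74 and 300, with sgMETTL16-2. Among called enriched windows, higher calls made up 85.8% in replicate 2 of sgMETTL16-1, and 62.8% and 87.1% for sgMETTL16-2. After the shift by the enriched median, calls were 114 lower and 54 higher, then 148 and 86, in the tables of sgMETTL16-1, and 839 lower and 153 higher, then 127 and 61, in those of sgMETTL16-2.

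Windows called higher lay more often within 1000 bases of the annotated 5′ end of their gene than uncalled windows in 3 of 4 tables. The shares were 20.0% against 13.1% in replicate 2 of sgMETTL16-1 (Fisher's exact test, two-sided, adjusted p = 0.000272). For sgMETTL16-2 they were 18.5% against 11.6% in replicate 1 (exact adjusted p = 2.88e-06) and 20.8% against 13.5% in replicate 2 (exact adjusted p = 0.000177). Lower windows were near the 5′ end less often in replicate 1 of sgMETTL16-2 (5.22% against 11.6%, exact adjusted p = 9.37e-08), while in the other 3 tables their share was not distinguishable from that of uncalled windows. Near the 3′ end, lower windows of replicate 1 of sgMETTL16-1 (35.9% against 25.9%, exact adjusted p = 0.00219) and higher windows of both replicate 2 tables (33.0% against 24.3% and 35.2% against 24.8%, exact adjusted p = 0.00023 and 1.58e-05) were over-represented. None of the 3′ differences passed when enriched windows alone were compared, a test added after seeing the data, with adjusted p of 1, 0.66 and 0.0907, whereas the 5′ differences of the higher windows did. Higher windows were long, with a median of 551 bases in replicate 2 of sgMETTL16-1 and 569 and 599 bases for sgMETTL16-2, against 121 over all windows. Length was not matched, so it was not separated from position. The replicate 2 tables shared 181 higher calls, so the 3 tables are not independent results. Exons, introns and untranslated regions were not annotated here.

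Of the 16 gene lists, cytoplasmic ribosomal protein genes had the most calls. The background was not matched on depth or expression, so a list of abundant RNAs may gain calls in either direction. The median of the list was -0.12 and -0.15 in the replicate 1 tables of sgMETTL16-1 and sgMETTL16-2, and 0.02 and 0.05 in the replicate 2 tables. In the replicate 1 tables, 27 of 79 were called lower with each guide, with adjusted p of 8.74e-29 for sgMETTL16-1 and 2.71e-16 for sgMETTL16-2 (Fisher's exact test over 128 tests). In the replicate 2 tables, 10 of 69 and 7 of 71 were lower (exact adjusted p = 4.27e-09 and 9.52e-06) and 12 and 15 were higher (exact adjusted p = 2.77e-06, lost after the shift at 0.251, and 6.53e-09). In replicate 1 of sgMETTL16-1, 4 were higher too (exact adjusted p = 0.00184). With sgMETTL16-1, RPL32, RPL37A and RPL30 were called lower in both tables, RPL30 at -0.18 and -0.54 in the authors' deposited tables, and RPL37A and RPL30 lost the replicate 1 call after the shift. RPL8 was called higher in both tables of that guide, but lower in replicate 2 after the shift. In opposite directions were RPL19, RPL36, RPS3 and RPS4X. With sgMETTL16-2 no member was called in 1 direction in both, and RPL27, RPL38, RPS16 and RPS4X were called in opposite directions. Adjusted over the list alone, 38 and 13 members were lower with sgMETTL16-1 and 31 and 8 with sgMETTL16-2. In replicate 1 of sgMETTL16-1, the 1 table in which the shift works against lower calls, 16 members were still lower after it (exact adjusted p = 7.82e-18).

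Translation initiation factor genes were over-represented among lower calls in the replicate 1 tables, 6 of 37 with sgMETTL16-1 (exact adjusted p = 0.000135) and 12 of 37 with sgMETTL16-2 (exact adjusted p = 4.53e-07). In replicate 2, 1 of 36 and 2 of 37 were lower (exact adjusted p = 0.529 and 0.0984). Adjusted over the list alone, the replicate 1 tables had 17 and 15 lower genes. EIF4A1 was lower in both tables of both guides. PABPC1, the cytoplasmic poly(A)-binding protein, was lower with sgMETTL16-2 at -0.64 and -0.49 in the authors' deposited tables. The same guide had EIF3A (0.20 and 0.28), EIF3B (0.34 and 0.34) and EIF4G1 (0.45 and 0.25) higher in the authors' deposited tables, and none of the 3 kept both calls after the shift. EIF3A was lower in replicate 1 and higher in replicate 2 with sgMETTL16-1, and EIF1 likewise with sgMETTL16-2. The list was also over-represented among higher calls in replicate 1 of sgMETTL16-1 (4 genes, exact adjusted p = 0.000135) and replicate 2 of sgMETTL16-2 (5 genes, exact adjusted p = 0.0143, lost after the shift at 0.454 and against genes with enriched windows at 0.182). These were 5 and 9 adjusted over the list alone. The median of the list was -0.11 and -0.04 in these tables, and PABPC1 had both a lower and a higher window in the first.

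Abundant nuclear and long non-coding RNAs were over-represented among lower calls in every table: 5 of 15 and 3 of 14 with sgMETTL16-1 (exact adjusted p = 2.1e-05 and 0.00144), and 6 of 14 and 3 of 14 with sgMETTL16-2 (exact adjusted p = 0.000135 and 0.00113). The counts were 6, 3, 7 and 3 adjusted over the list alone. In replicate 2 of sgMETTL16-1 the median of the list was 0.03. MALAT1, a nuclear speckle RNA known to bind METTL16, and NEAT1, the scaffold of paraspeckles, were lower in both tables of both guides. After the shift NEAT1 lost its call in replicate 1 of sgMETTL16-1, where 2 genes of the list were still lower (exact adjusted p = 0.0332). NEAT1 was at -0.34 and -0.43 with sgMETTL16-1 in the authors' deposited tables. SNHG1, a host gene of small nucleolar RNAs, was lower in both tables of sgMETTL16-2, at -0.77 and -1.14 in the authors' deposited tables.

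Genes of myeloid differentiation were over-represented among higher calls with sgMETTL16-2, 6 of 31 in replicate 1 (exact adjusted p = 0.00594, lost after the shift at 0.168) and 4 of 32 in replicate 2 (exact adjusted p = 0.0404, lost against genes with enriched windows at 0.144 and with an FDR of 0.01 at 0.065). These were 7 and 4 adjusted over the list alone. The 6 were CEBPA, CEBPB, CEBPE, CTSG, GFI1 and SPI1, named after their values were seen. CTSG, 1 of the 4 in replicate 2, also had a lower window there. With sgMETTL16-1, 1 of 31 myeloid genes was higher in each table (exact adjusted p = 0.29 and 0.96). AML and leukaemia stem cell genes were over-represented among higher calls in replicate 1 of sgMETTL16-2 (7 of 38, exact adjusted p = 0.0034; 7 adjusted over the list alone), where its median was -0.10. In replicate 2 of that guide 3 of 37 were higher (exact adjusted p = 0.206) and the median was -0.08. CD93 (0.23 and 0.20) was higher in both of that guide's authors' deposited tables, though this window was called in neither after the shift. CEBPA belongs to both lists and was the 1 member called higher in both tables of sgMETTL16-1. After the shift the AML list still passed (exact adjusted p = 0.0342).

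Integrated stress response genes were over-represented among higher calls in 3 of 4 tables, with 4 of 20 called in each (exact adjusted p = 0.00944 in replicate 2 of sgMETTL16-1, and 0.0276 and 0.00944 for sgMETTL16-2), and all were lost after the shift, at 1, 0.468 and 0.33, and against genes with enriched windows, at 0.101, 0.64 and 0.101. The call in replicate 1 of sgMETTL16-2 was also lost with an FDR of 0.01, at 0.71, and with a two-sided p, at 0.288. In replicate 2 of sgMETTL16-1 the median of the list was -0.06. Adjusted over the list alone the counts were 4, 5 and 9. SLC7A1 was in all 3, and ATF4 was called in replicate 2 of sgMETTL16-1, at 0.35 in the authors' deposited table.

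Genes of S-adenosylmethionine and methionine metabolism were over-represented among lower calls in replicate 1 of sgMETTL16-1, where ADI1, MAT2A and SRM were called (3 of 24, exact adjusted p = 0.0229, lost after the shift at 0.0686, against genes with enriched windows at 0.257 and with an FDR of 0.01 at 0.0772; 4 adjusted over the list alone). The median of the list was 0.01 there. MAT2A was the 1 member called in both tables of a guide. Genes of m6A writers, erasers and readers were over-represented among lower calls in replicate 1 of sgMETTL16-1 (4 of 28, exact adjusted p = 0.00454). They were so among higher calls in replicate 2 of sgMETTL16-2 (4 of 25, exact adjusted p = 0.0202, lost after the shift at 0.383 and against genes with enriched windows at 0.228), where the median of the list was -0.03. These were 6 and 5 adjusted over the list alone. The demethylase gene ALKBH5 (0.39 and 0.49) and the writer adaptor gene RBM15B (0.40 and 0.30) were higher in both of the authors' deposited tables of sgMETTL16-2. After the shift ALKBH5 was called in neither and RBM15B in 1 of them. ZC3H13 was called lower in replicate 1 and higher in replicate 2 with each guide. HNRNPA2B1 was called lower in both tables of sgMETTL16-1, at -0.22 and -0.41 in the authors' deposited tables, although a second window of it was higher in replicate 2 and its replicate 1 call was lost after the shift.

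Spliceosome genes were over-represented among lower calls in replicate 1 of sgMETTL16-2 (6 of 37, exact adjusted p = 0.022, lost against genes with enriched windows at 0.312 and with an FDR of 0.01 at 0.234 or a two-sided p at 0.0906), 6 adjusted over the list alone. The median of the list was 0.04 there, and SRSF11 was the member lower in both tables of both guides. In replicate 2 of sgMETTL16-2 the list leaned the other way, with a median of 0.13. There 4 of 38 were higher and 2 lower (exact adjusted p = 0.0638 and 0.0984). SRSF7 was called in opposite directions in the 2 tables of that guide. Cell cycle genes were over-represented among higher calls in replicate 2 of sgMETTL16-2 (5 of 41, exact adjusted p = 0.0205, lost after the shift at 0.0686 and against genes with enriched windows at 0.144), 5 adjusted over the list alone. CCND3 (0.29 and 0.31) was higher in both of that guide's authors' deposited tables, as was MKI67, but neither shared window was called in either table after the shift. The topoisomerase gene TOP2A was lower in both of the authors' deposited tables of sgMETTL16-1 (-0.35 and -1.29), and its replicate 1 call was lost after the shift. With a two-sided p alone TOP2A lost both calls. No table passed the test for branched-chain amino acid metabolism, p53 and apoptosis, DNA damage repair, or interferon and innate immunity, and none of their members was called in 1 direction in both tables of a guide. Each of these lists had at most 3 genes called in a table and direction adjusted over the list alone. Markers of lymphoid and erythroid cells, the other blood cell types, had 1 call in all, NKG7 at -0.69 in replicate 2 of sgMETTL16-2 in the authors' deposited table. The list of mitochondrially encoded genes had no window to test. The list tests treat genes as independent, which they are not, and their background was not matched on depth or expression. They describe the libraries behind each table.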

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

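No paired analysis was possible because the tables hold no value per library, although the labels share replicate numbers. The motif alternatives, the alternatives for counts or normalized values, and the replicate block were not run for the same lack of values or of a genome. Centring on the median moved nothing, because that median is 0 in each table. The shift by the enriched median, which lowers all windows of a table alike except in replicate 1 of sgMETTL16-1, where it raises them, turned the balance of calls in the replicate 2 tables, from 119 lower and 416 higher to 148 and 86 for sgMETTL16-1 and from 104 and 410 to 127 and 61 for sgMETTL16-2. No list or position test other than those below crossed 0.05.

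Windows shared by the tables of sgMETTL16-1 were 9 lower and 4 higher. They became 17 lower with any overlap, 4 lower and 2 higher with an overlap of 0.8, 0 and 2 with a fold enrichment of at least 2, and 19 and 10 counted by gene. The 4 higher ones became 2 with an FDR of 0.01, 2 with a two-sided p and 1 after the shift by the enriched median. Those of sgMETTL16-2, 13 lower and 112 higher, became 2 and 67 with an overlap of 0.8, 1 and 48 with a fold enrichment of at least 2, and 21 and 12 after the shift. Its lower ones became 26 by gene and its higher ones 60 with an FDR of 0.01. Those shared by all 4 tables, 3 and 3, became 8 lower and 6 higher by gene, leaving out genes also called the other way. The 3 lower became 6 with any overlap, 1 with an overlap of 0.8 and 0 with a fold enrichment of at least 2. The 3 higher became 1 each with an FDR of 0.01, a two-sided p or the shift. All 6 counts became 0 with an absolute log2 fold change of at least 1. With either replicate left out, lower calls ranged from 119 to 223 and higher ones from 59 to 416 for sgMETTL16-1. For sgMETTL16-2 they ranged from 104 to 731 and from 410 to 663, and for both guides from 40 to 107 and from 10 to 181.

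In single tables, in the order replicate 1 and 2 of sgMETTL16-1, then of sgMETTL16-2, lower calls were 223, 119, 731 and 104 and higher calls 59, 416, 663 and 410. An FDR of 0.01 left 131, 60, 409 and 58 lower and 38, 251, 327 and 246 higher. An absolute log2 fold change of at least 1 left 26, 54, 380 and 48 lower and 11, 29, 73 and 23 higher. A fold enrichment of at least 2 left 27, 11, 170 and 10 lower and 11, 126, 252 and 150 higher. Enriched windows alone left 65, 340 and 58 lower in the last 3 tables. A two-sided p left 77 lower in replicate 2 of sgMETTL16-1 and 433 higher in replicate 1 of sgMETTL16-2. The shift left 114 lower in the first table and 86, 153 and 61 higher in the others.

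Between guides, rho of 0.563 in replicate 1 became 0.859 over windows called in at least 1 table, 0.683 with an overlap of 0.8 and 0.668 over enriched windows. In replicate 2, 0.604 became 0.709 over called windows and 0.715 with an overlap of 0.8. Over called windows, 0.0698 between replicates of sgMETTL16-1 became 0.236, and 0.0775 between its replicate 1 and replicate 2 of sgMETTL16-2 became 0.318. Over enriched windows, 0.146 between replicates of sgMETTL16-2 became 0.27, and 0.0698 between those of sgMETTL16-1 became 0.133. Between different guides and numbers, 0.139 became 0.231 and 0.0775 became 0.124 over enriched windows, and 0.139 became 0.21 over called windows. The median log2 fold change of 0 became 0.13 in replicate 2 of sgMETTL16-1, and 0.13 and 0.14 for sgMETTL16-2, over enriched windows. The adjusted p of the 3′ end went from 0.00219 to 1, from 0.00023 to 0.66 and from 1.58e-05 to 0.0907 over enriched windows. The MAT2A window of replicate 2 of sgMETTL16-1, at -0.81 in the authors' deposited table, was not called with an FDR of 0.01.

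For the lists, exact adjusted p values moved across 0.05 as follows. With an FDR of 0.01, methionine metabolism went from 0.0229 to 0.0772, the spliceosome from 0.022 to 0.234, the stress response in replicate 1 of sgMETTL16-2 from 0.0276 to 0.71 and myeloid genes in replicate 2 from 0.0404 to 0.065. In the other direction went m6A genes among higher calls of replicate 2 of sgMETTL16-1, from 0.102 to 0.0423, and initiation factors among those of replicate 1 of sgMETTL16-2, from 0.0506 to 0.0317. With a two-sided p the spliceosome went to 0.0906 and the stress response in replicate 1 of sgMETTL16-2 to 0.288. It took AML genes from 0.0542 to 0.0206 and the cell cycle from 0.0767 to 0.0317 among higher calls of replicate 2 of sgMETTL16-1, and m6A genes from 0.0984 to 0.0396 among lower calls of replicate 1 of sgMETTL16-2. With genes that have enriched windows as background, methionine metabolism went to 0.257, the spliceosome to 0.312 and the stress response from 0.00944, 0.0276 and 0.00944 to 0.101, 0.64 and 0.101. In replicate 2 of sgMETTL16-2 the same background took m6A genes among higher calls from 0.0202 to 0.228, myeloid genes to 0.144, initiation factors from 0.0143 to 0.182 and the cell cycle from 0.0205 to 0.144. After the shift, methionine metabolism went to 0.0686, ribosomal proteins among higher calls of replicate 2 of sgMETTL16-1 from 2.77e-06 to 0.251, myeloid genes in replicate 1 of sgMETTL16-2 from 0.00594 to 0.168, and the stress response to 1, 0.468 and 0.33. In replicate 2 of sgMETTL16-2 the shift took m6A genes to 0.383, initiation factors to 0.454 and the cell cycle to 0.0686 among higher calls. Among lower calls it took initiation factors from 0.529 to 0.0329 and from 0.0984 to 0.0257 in the replicate 2 tables, and m6A genes from 0.0984 to 0.0155 in replicate 1 of sgMETTL16-2.

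With random lists not matched, the percentile of AML genes went from 44.2 to 38.7 in replicate 1 of sgMETTL16-1, and from 38.8 to 23.6 and from 20.5 to 15.2 with sgMETTL16-2. That of m6A genes went from 44.6 to 36.0 in replicate 2 of sgMETTL16-1, and from 29.6 to 23.0 and from 48.2 to 35.7 with sgMETTL16-2. In replicate 1 of sgMETTL16-2, DNA damage repair went from 24.6 to 15.4 and interferon genes from 46.1 to 54.9, and in replicate 2 initiation factors went from 15.9 to 26.6.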

Other observations

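By their median log2 fold change over members, ribosomal protein genes stood at the 1.09 and 1.51 percentile of random lists in the replicate 1 tables of sgMETTL16-1 and sgMETTL16-2, and at 82.2 and 88.3 in the replicate 2 tables. Myeloid differentiation genes stood at 97.505 and 96.96 with sgMETTL16-2, against 40.8 and 73.1 with sgMETTL16-1, and the difference between guides was not tested. DNA damage repair genes, which had few calls, stood at 1.86 in replicate 2 of sgMETTL16-2 and at 68.0 in replicate 2 of sgMETTL16-1. Other lists came near these ends in single tables. Cell cycle genes stood at 97.35 in replicate 2 of sgMETTL16-1. With sgMETTL16-2, spliceosome genes stood at 97.1 in replicate 2 and abundant nuclear and long non-coding RNAs at 3 in replicate 1. These percentiles were not adjusted for the number of lists and tables. Apart from the replicate 1 table of sgMETTL16-1, 61 windows were called higher and 4 lower in the 3 remaining tables, and 42 of the 61 lay above 0 in that table too. Of the 6879 windows matched in all 4 tables, 946 were below 0 and 1341 above 0 in each.

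Of the tests that follow, those on a common change as the whole cause, on the shared controls of replicate 1 and on the whole MAT2A transcript were chosen after their results had been seen; the others were fixed before. The first pattern is that log2 fold changes agree within a replicate number and hardly within a guide. The largest covariance between different numbers was 0.201 of the smallest within a number, which restates the pattern and decides nothing about a change common to the knockouts. Better matched window boundaries within a number are argued against as the whole cause. On 871 windows that overlap by 0.8 in all 4 tables, the smallest rho within a number was 0.652. It still exceeded the largest across numbers, 0.307, by 0.345. That 0.307 is above the largest value across numbers over all matched windows, 0.146, so boundaries may account for part of the low agreement across numbers. Libraries of sgNS shared by the tables of 1 number may account for much of it: windows without enrichment gave a rho of at least 0.594 within a number and at most 0.105 across numbers. An effect of METTL16 loss common to all tables stays open.

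The second pattern is that higher calls outnumber lower ones at enriched windows in 3 of the 4 tables. A factor for the whole immunoprecipitation of a library was not separated from other causes. After the enriched median was subtracted, the share of higher calls among called enriched windows fell from 85.8%, 62.8% and 87.1% to 46.8%, 24.1% and 41.9%, the first and highest being sgMETTL16-1 in replicate 2. The subtraction itself pulls these shares down, and a true rise of m6A at most sites would be removed by it too, so the 2 explanations cannot be told apart. Whether the sgNS libraries of replicate 1 contribute stays open: sgMETTL16-2 lay above sgMETTL16-1 there by a median of 0.105 over 4333 windows, but single libraries have no replicate spread to set this against.

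The third pattern is the lower 3′ window of MAT2A in all 4 tables. Chance could not be excluded by rank: 2.54% of the 21172 windows that overlap in all 4 tables, or 538, had every log2 fold change as low as the highest MAT2A value, and 130 were as far above 0. Many of these windows may be thinly covered, and their depth is unknown. A change of the whole MAT2A transcript cannot be told apart from one at its 3′ end, because the upstream window was higher by over 2 approximate standard errors in 1 table of 4. A change in reads of GGCX on the other strand was not tested. Loss of METTL16 activity at the MAT2A 3′ end remains an open hypothesis.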
